A study of Mus musculus with 18 samples.

How the data were processed

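The study profiled ribosomes in mouse erythroblasts from fetal liver, the cells that give rise to red blood cells. The labels give the strain as FVB/n x C57BL/6 and the genotype as Trp53 -/-, and say that the cells grew in StemPro medium with erythropoietin, stem cell factor and dexamethasone. Tunicamycin (2.5 ug/ml for 1.5 h) blocks N-glycosylation in the endoplasmic reticulum (ER) and was used, per the series design, to induce phosphorylation of the initiation factor eIF2. Each treatment was measured in 3 kinds of library: total RNA, footprints of ribosomes frozen with cycloheximide (100 ug/ml for 5 min), and footprints of ribosomes held at start sites with harringtonine (2 ug/ml). The 18 samples form 6 groups of 3. RNA was extracted with an RNeasy Plus kit, and libraries were made with the NEBNext small RNA set for footprints and TruSeq for RNA, per the labels' protocols.

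The deposited table held raw counts of cycloheximide footprints for the 5' leader (5' UTR), coding sequence (CDS) and 3' UTR of 20683 genes, and raw counts of RNA reads per gene. The deposited harringtonine files held read counts at 9025 single positions, 4639 on the forward and 4386 on the reverse strand. STAR, HTSeq and edgeR, with builds mm10 and GRCm38, are named in the submitters' processing notes; versions and counting options are not given in the sources used here. Every harringtonine position carried at least 20 reads summed over the 3 libraries of 1 treatment, so their totals describe kept positions and not sequencing depth. The RNA count of a gene was the same on each of its feature lines and was used once. How a read that is leader in 1 transcript and coding in another was counted is not given in the sources used here. The reference tables matched 20585 gene symbols (RefSeq genes, GRCm38.p6) and 19953 symbols (gene names). A genome sequence was not used here, so codons at start sites were not read, and coverage tracks named in the labels were not analysed here.

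Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr (minimum count 10, minimum total 15), glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 counted as passing. Rises and falls are named only for genes or lists that passed. In RNA, CDS footprints, harringtonine reads and translational efficiency TMM sets the typical gene near 0, so rises and falls there are relative to it. A change common to all mRNAs cannot be seen in them. Every adjusted p of a gene or site in the results comes from this edgeR quasi-likelihood test unless another tool is named. RNA, cycloheximide CDS and harringtonine counts were each compared between 3 tunicamycin and 3 untreated libraries. Translational efficiency, the ratio of CDS footprints to RNA, was tested as the interaction of assay and treatment in 1 model over 12 libraries, and harringtonine reads against RNA likewise. The leader share was tested as the interaction of feature (leader or CDS) and treatment within the 6 cycloheximide libraries, with the library as a term and 1 TMM factor per library from its summed leader and CDS counts. Its log2 values are changes of the ratio of leader to CDS footprints, not of the percent. Harringtonine counts per gene are sums of the deposited positions; the design had foreseen counts over whole genes. Positions within 10 nt were merged into 7663 sites. The sources tie each harringtonine column to a treatment, and its number was not matched to the numbers of other libraries.

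Gene lists written before the data were examined were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of 5 or more measured members within a comparison. The estimated correlation was run beside it. The list of mitochondrially encoded genes had 0 members in the table. Values are means with SD over 3 libraries as reads scaled to the library total (CPM), and fold changes are log2 with the standard error (SE) of the fit. Single values of 3 against 3 libraries were compared with a 2-sided exact permutation test, whose smallest p is 0.1. The p-values measure only the spread between these samples, since the labels do not say whether the 3 samples of a group were separate cultures or animals.

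The tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, among passing genes with a mean of at least 5 CPM in each assay and no overlap between treatments, the 12 largest increases and 12 largest decreases. Where none passed, it took the 3 with the smallest p as not passing. It added Atf4, Ddit3, Ppp1r15a, Ifrd1, Hspa5 and Trp53, up to 4 members of each list with the smallest p, and the 10 highest harringtonine sites with a gene. Results of 2 genes that this rule named are not reported here. Alternatives changed the scaling, the tool (DESeq2 1.42.0, limma voom, robust edgeR), the filter, the threshold or the replicate block, or left out 1 library. Removal of a gene span trend, a TMM factor per column for the leader share, a fit without histone genes and a fit without the libraries numbered 1 were added after the data were seen. Gene span is genomic, introns included.

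Samples carry replicate numbers. In RNA, deviations from the group means correlated at 0.416, 0.312 and 0.191 between the 2 libraries numbered 1, 2 and 3 (10643 genes). The highest correlation with a library of another number was -0.121, 0.190 and 0.190. Each own value was above 0.1, so these numbers were taken to pair the RNA samples. For number 3 the own and other values hardly differed, so that pair is weakly backed. The pairing comes from this check and not from the labels, and blocked fits rest on it. Replicates differed by more than counting error: chi-square per degree of freedom between replicates was 4.13 to 18.7. The tests were tried on simulated counts with 200 genes changed 2-fold. Each simulated library was drawn on its own, without the correlations between libraries given above, so the shares may not hold for the data. They recovered 93% of these in RNA, 87.5% in cycloheximide footprints, 85.5% in translational efficiency, 25.5% in harringtonine footprints, 54.5% in harringtonine against RNA, 29% in the leader share and 3.5% of sites. Genes called without a planted change made up 9.27%, 7.89%, 3.39%, 5.56%, 4.39%, 1.69% and 0% of the calls, in that order. In the data the leader share shifted in most genes, unlike in the simulation, so its recovery may not describe that test. Columns of values left unused numbered 0.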

Results

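Total RNA, cycloheximide footprints and harringtonine footprints were measured in erythroblasts left untreated or given tunicamycin, in 6 groups of 3 libraries. Totals are in mega reads (M). RNA totals were 30.8 M, 49.0 M and 12.9 M reads in untreated libraries 1 to 3 and 14.5 M, 29.2 M and 43.5 M under tunicamycin. Cycloheximide footprints on annotated features came to 7.16 M, 6.90 M and 6.93 M untreated and 5.49 M, 5.03 M and 5.79 M under tunicamycin. Reads at kept harringtonine positions came to 0.524 M, 0.447 M and 0.482 M untreated and 0.648 M, 0.559 M and 0.591 M under tunicamycin. Of the 20683 genes in the count table, 5778 had no RNA read and 7871 had no CDS footprint.

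Trp53, which encodes the tumour suppressor p53, had RNA reads in every library, from 1426 to 6060, and from 223 to 296 CDS footprints in each cycloheximide library. It did not pass in RNA (log2 -0.07 ± 0.08 SE, edgeR adjusted p = 0.764) or footprints (0.39 ± 0.12, 0.101). Counts per gene do not show which part of a gene is deleted, so they leave the genotype label unchecked. Red-cell genes for haem synthesis, iron uptake and the membrane skeleton summed to 10848 ± 252 CPM of RNA in untreated and 10856 ± 183 CPM in tunicamycin-treated cells (SD, n = 3), led by the carbonic anhydrase gene Car2. No marker of macrophages, neutrophils and monocytes, hepatocytes, or endothelium and stroma reached 5 CPM of RNA. The highest of each list were Cd68 (0.803 CPM), Prtn3 (0.138), Apoa1 (1.47) and Pdgfrb (0.310). Megakaryocyte markers summed to 151 ± 7.80 and 136 ± 8.83 CPM, mostly the platelet glycoprotein gene Gp5 (100 CPM), and mast cell markers to 179 ± 38.9 and 181 ± 40.6 CPM, mostly the IgE receptor gene Ms4a2 (139 CPM). The globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were listed at 0 in the count table for RNA and CDS footprints but held 4481, 70, 266981 and 20894 harringtonine reads.

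To see which transcripts had responded by 1.5 h, RNA was compared between treatments. Chac1, a glutathione-degrading enzyme and a target of the transcription factor ATF4, rose most, from 3.81 ± 0.254 to 27.9 ± 6.58 CPM (SD, n = 3, log2 2.87 ± 0.17 SE, edgeR adjusted p = 1.8e-05). Herpud1, a component of ER-associated degradation, rose by 1.36 ± 0.09 from 37.5 to 94.8 CPM, and the ER chaperone gene Hspa5 (BiP) by 0.78 ± 0.08 from 512 to 876 CPM. The stress regulators Trib3, Ddit3 (CHOP) and Atf3 rose by 0.88 ± 0.10, 0.85 ± 0.13 and 0.92 ± 0.14, Atf3 at 4.60 CPM. Txnip (0.67 ± 0.11), the polymerase subunits Polr2a (0.65 ± 0.09) and Polr1a (0.49 ± 0.07), the dynein heavy chain gene Dync1h1 (0.57 ± 0.08), the nuclear pore gene Tpr (0.55 ± 0.07), the splicing factor gene Prpf8 (0.53 ± 0.08), the scaffold gene Iqgap1 (0.47 ± 0.08) and the immediate early gene Ier2 (0.39 ± 0.06) also rose. Atf4 itself (0.16 ± 0.07, adjusted p = 0.401), Ppp1r15a (0.13 ± 0.08, 0.529) and Ifrd1 (0.02 ± 0.08, 0.937) did not pass in RNA.

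In all, 16 of 10643 genes tested rose in RNA and 0 fell by edgeR, with 1324 at an unadjusted p under 0.05 and 112 passing by DESeq2. With the replicate number as a block 410 passed (283 up, 127 down), among them each of the 16. The lower genes with the smallest p, none passing, were the cell cycle inhibitor gene Cdkn2c (log2 -0.37 ± 0.07, adjusted p = 0.0818, blocked 0.0171), Mospd3 (-0.33 ± 0.06, 0.0818, blocked 0.01) and the phosphatase gene Pdxp (-0.32 ± 0.06, 0.0993, blocked 0.0163). Leaving out untreated replicate 2, untreated replicate 3, tunicamycin replicate 2 or tunicamycin replicate 3 left 3 genes each, and leaving out tunicamycin replicate 1 gave 26, 1 of them lower. Chac1, Herpud1 and Hspa5 passed in each alternative that tested them. Ddit3 did not pass without untreated replicate 2 (adjusted p = 0.167) or 3 (0.173) or tunicamycin replicate 2 (0.255) or 3 (0.270). Of 19 alternatives in RNA, 11 ended the call for Iqgap1, 11 for Ier2, 8 for Txnip, 7 for Polr1a, 7 for Ddit3, 6 each for Dync1h1, Tpr and Prpf8 and 5 for Polr2a. Trib3 lost its call under 4 of 18 (up to 0.0918) and Atf3 under 5 of 17 (up to 0.303).

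ATF4 targets rose as a list in RNA (27 measured): Chac1, Trib3 and Atf3 rose, 0 fell and 24 did not pass, with 10 up adjusted over the list alone (camera adjusted p = 1.04e-07, adjusted p = 0.0614 with an estimated correlation). ER chaperones and degradation factors rose as a list (29 measured, Herpud1 and Hspa5 up, 10 up adjusted over the list alone, 1.04e-07, adjusted p = 0.174 with an estimated correlation). Pdia4 (0.71 ± 0.16, adjusted p = 0.178, blocked 0.00135) and Hsp90b1 (0.43 ± 0.11, 0.211, blocked 0.00533), which encode ER folding enzymes, did not pass singly. Cytosolic tRNA synthetases rose as a list with small member changes (20 measured, 0 passing and 0 adjusted over the list alone, median 0.11, 3.95e-05, adjusted p = 0.0614 with an estimated correlation), for example Nars 0.19 ± 0.06, Tars 0.18 ± 0.06 and Eprs 0.24 ± 0.06 (blocked 0.0299). Immediate early genes rose (19 measured, Ier2 up, 6 up adjusted over the list alone, 0.000453, adjusted p = 0.0698 with an estimated correlation), and Egr1 was at 0.82 ± 0.15 (adjusted p = 0.0818, blocked 0.00346).

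Translation elongation and other TOP mRNAs, whose 5' oligopyrimidine tract couples them to growth signals, rose as a list in RNA (15 measured, 0 passing and 0 adjusted over the list alone, median 0.12, adjusted p = 0.00575, adjusted p = 0.383 with an estimated correlation, 0.128 without tunicamycin replicate 2). G2/M cell cycle genes rose (23 measured, 0 passing, 6 up adjusted over the list alone, among the leaders Mki67 at 0.41 ± 0.07 (blocked 0.0236) and Cenpe at 0.42 ± 0.08 (blocked 0.00481), adjusted p = 0.0303, adjusted p = 0.383 with an estimated correlation). The G2/M list did not pass with the block (0.0598) or without untreated replicate 3 (0.0553) or tunicamycin replicate 2 (0.0719) or 3 (0.126). Cholesterol synthesis genes did not pass (22 measured, adjusted p = 0.0650) but did with the block (0.0376). The eIF2 uORF list (19 measured, adjusted p = 0.705), ribosomal proteins (78, 0.419), erythroid haem and membrane genes (24, 0.733), erythroid transcription factors (19, 0.133), oxidative phosphorylation genes (45, 0.0806), p53 targets (17, 0.634), eIF2 kinases and subunits (16, 0.132) and megakaryocyte markers (6, 0.613) did not pass in RNA by camera. Adjusted over the list alone, 2 members of the eIF2 uORF list were up and 1 down (1 up over all genes), 2 of the cholesterol list and 1 of the haem list up, 1 megakaryocyte marker down (0 over all genes) and 0 of the other lists. The haem list had a median of -0.04 and a mean of 0.01, and megakaryocyte markers 0.02 and -0.03.

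Cycloheximide footprints on coding sequences show which proteins were being made. Atf4, a transcription factor whose upstream reading frames hold back its translation until eIF2 is phosphorylated, rose from 75.9 ± 2.22 to 343 ± 54.3 CPM (SD, n = 3, log2 2.18 ± 0.11 SE, edgeR adjusted p = 2.33e-08). Ddit3 rose from 5.26 ± 0.999 to 28.6 ± 8.75 CPM (2.45 ± 0.23), the eIF2 phosphatase subunit Ppp1r15a (GADD34) from 14.2 ± 2.75 to 30.1 ± 6.93 CPM (1.1 ± 0.18) and the regulator Ifrd1 from 88.4 ± 6.86 to 167 ± 19.7 CPM (0.93 ± 0.10). Ibtk rose by 1.07 ± 0.16. These 5 genes passed under each of the 20 alternatives. Hspa5 footprints were at 1767 ± 122 and 2154 ± 181 CPM and did not pass (0.29 ± 0.09, adjusted p = 0.108), though it passed under 4 of 20 alternatives. Chac1, at 3.92 CPM, rose by 2.04 ± 0.32, Herpud1 by 0.72 ± 0.14 and Trib3 by 0.72 ± 0.16. Of 20 alternatives, 4 ended the call for Herpud1 (adjusted p up to 0.108) and 5 for Trib3 (up to 0.170).

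Among the other large increases were Fbxl12 (1.98 ± 0.31), Med24 (1.70 ± 0.31), the ATP synthase subunit gene Usmg5 (1.51 ± 0.19), Scoc (1.47 ± 0.19), Kcnh3 (2.18 ± 0.28), Tacr3 (2.10 ± 0.40) and the histone genes Hist1h4n (1.77 ± 0.35), Hist1h3f (1.64 ± 0.18), Hist1h3h (1.50 ± 0.15) and Hist1h2ag (1.50 ± 0.17). Several of these counts are uncertain. Kcnh3 and Tacr3 had 610 and 651 CDS footprints over 6 libraries but 3 and 0 RNA reads. Leader and CDS counts were nearly equal for Fbxl12 (293 and 301 reads) and Hist1h2ag (17299 and 17274) and close for Usmg5 (3980 and 3374), and a read lying in both features would be counted in each. Med24 and Tacr3 did not pass with robust edgeR (adjusted p = 0.277 and 0.273) or DESeq2 (0.0848 and 0.232). Near-identical copies make single histone counts uncertain.

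Decreases were smaller. Footprints fell on the centriole gene Sclt1 (-0.95 ± 0.23), Pitpnm2 (-0.79 ± 0.19), the kinase gene Mast2 (-0.75 ± 0.17), Prdm4 (-0.72 ± 0.18), Mllt1 (-0.71 ± 0.12), the DNA annealing helicase gene Smarcal1 (-0.69 ± 0.11), Mapkapk5 (-0.66 ± 0.16), the laminin gene Lamc1 (-0.65 ± 0.11), the ribosomal protein genes Rpl37a (-0.64 ± 0.16) and Rps18 (-0.58 ± 0.12), the nuclear pore gene Nup210 (-0.58 ± 0.13) and Efr3a (-0.57 ± 0.09). Of 9265 genes tested, 165 rose and 74 fell relative to the typical gene. The count was 114 without untreated replicate 1, 58 without untreated replicate 2, 431 without tunicamycin replicate 1, 92 without tunicamycin replicate 2 and 60 without tunicamycin replicate 3. Mllt1, Smarcal1 and Lamc1 passed under each alternative. Of 19 alternatives, 10 ended the call for Prdm4, 8 for Pitpnm2 and 6 for Sclt1, and of 20, 8 for Rpl37a, 7 for Nup210, 6 for Mast2, 6 for Mapkapk5 and 4 for Rps18.

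Histone genes were frequent among the increases. Of 56 histone genes measured, 33 rose, 0 fell and the median change was 0.72 (edgeR, log2). Summed over copies, footprints went from 12747 ± 1546 to 21470 ± 4970 CPM (SD, n = 3, exact permutation p = 0.1), by 1.07 for H2A, 0.94 for H3, 0.79 for H4, 0.71 for H2B and 0.28 for the linker H1. Histone RNA, which lacks a poly(A) tail, was sparse, with 27611 reads over 6 libraries against 563581 footprints. Its median change over 49 histone genes was -0.52.

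**Figure D1:**
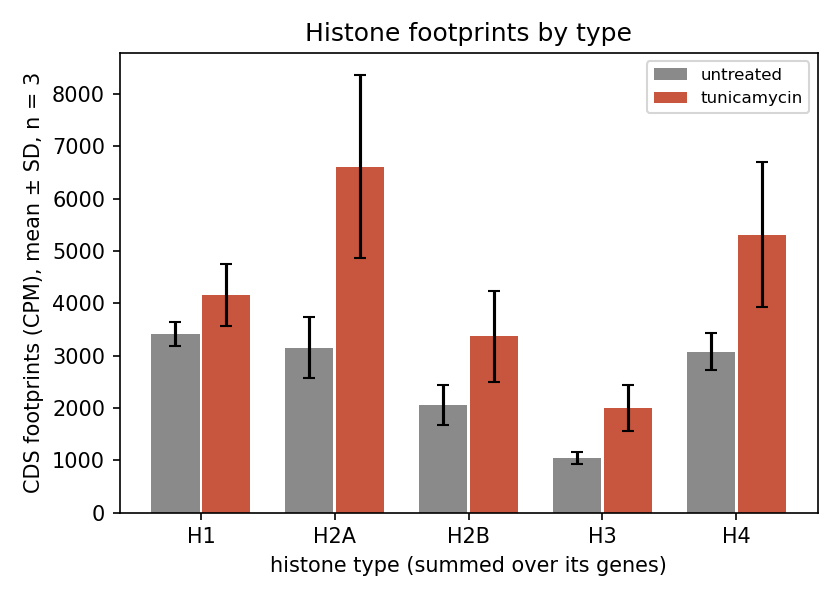
Bars give the mean footprints (CPM) summed over the genes of each histone type in untreated and tunicamycin-treated cells, with SD (n = 3). H2A went from 3156 to 6614 CPM and H1 from 3414 to 4159.

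**Figure D2:**
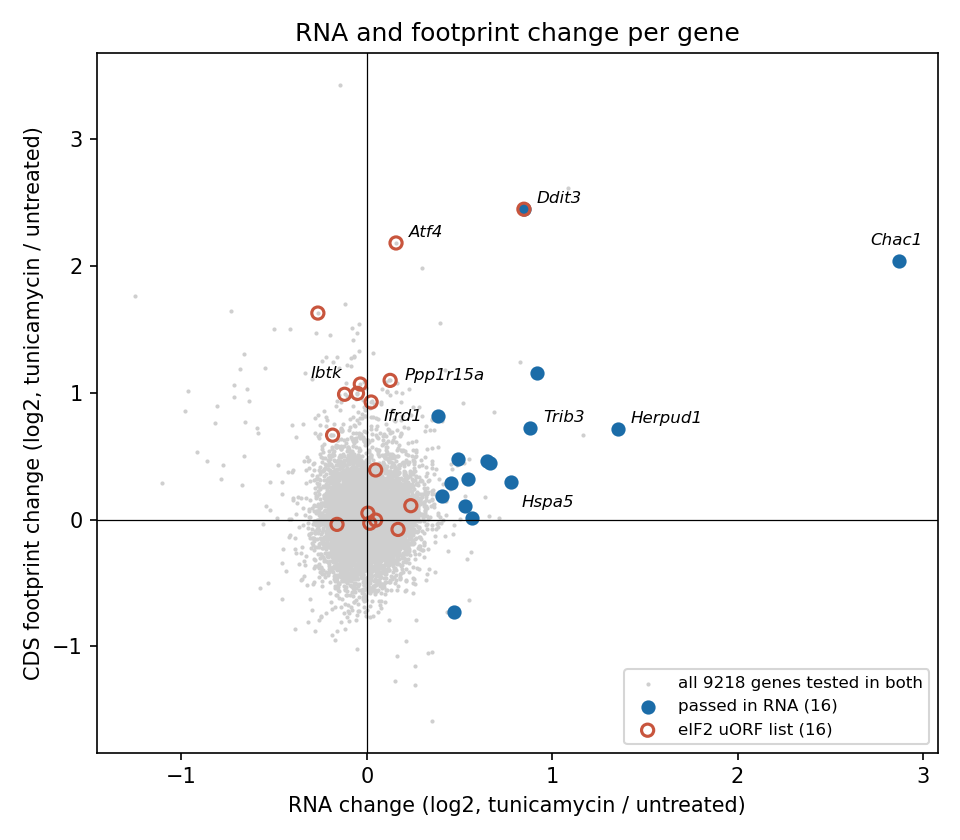
Each point is 1 of the 9218 genes tested in both assays, with the fitted RNA change (log2) on the horizontal and the fitted CDS footprint change (log2) on the vertical axis, and filled points are the 16 genes that passed in RNA and open rings the 16 measured members of the eIF2 uORF list. Atf4 lies at 0.16 in RNA and 2.18 in footprints, while Herpud1 lies at 1.36 and 0.72.

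Genes of the eIF2 uORF list, mRNAs with upstream reading frames known to keep being translated when eIF2 is phosphorylated, rose in footprints (16 measured: 8 up, 0 down, 8 not passing, 10 up adjusted over the list alone, median 0.80, camera adjusted p = 1.82e-09, adjusted p = 0.0716 with an estimated correlation). Immediate early genes rose (16 measured, 4 up, 9 up adjusted over the list alone, 1.1e-08, adjusted p = 0.0716 with an estimated correlation), with Ier2 at 0.82 ± 0.12, Klf6 at 0.51 ± 0.11, and Fosb (2.62 ± 0.56) and Egr1 (1.24 ± 0.26) at 2.24 and 4.21 CPM. Alternatives ended the call for Klf6 (6 of 20), Egr1 (6 of 18) and Fosb (4 of 18). Ribosomal protein genes fell as a list (47 measured: 3 up, 4 down, 6 up and 16 down adjusted over the list alone, median -0.22, mean -0.05, 0.0326, adjusted p = 0.647 with an estimated correlation), although Rpl41 (1.1 ± 0.18), Rps25 (0.70 ± 0.10) and Rplp1 (0.65 ± 0.13) rose. That list did not pass without untreated replicate 2 (0.111) or 3 (0.108) or tunicamycin replicate 1 (0.460) or 3 (0.263). The call for Rplp1 ended under 4 of 20 alternatives (adjusted p up to 0.111). TOP mRNAs fell (15 measured, 0 passing, 1 up and 6 down adjusted over the list alone, 0.0326, adjusted p = 0.579 with an estimated correlation), led by the poly(A) binding protein gene Pabpc1 (-0.79 ± 0.21, adjusted p = 0.0603) and Eef1g (-0.44 ± 0.12, 0.0612), each passing under 6 of 20 alternatives. The TOP list did not pass without untreated replicate 1 (0.141) or tunicamycin replicate 1 (0.0600) or 3 (0.179).

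ATF4 targets did not pass as a list in footprints (27 measured, Chac1, Trib3 and Atf3 up, adjusted p = 0.271), nor did ER chaperones (29, Herpud1 and Xbp1 up, 0.478) or tRNA synthetases (20, 0.412). Erythroid transcription factors (19, 0.0521), erythroid haem and membrane genes (25, the band 3 gene Slc4a1 up by 0.37 ± 0.09, 0.478), oxidative phosphorylation genes (43, with Ndufa5 0.49 ± 0.09, Cox6c 0.80 ± 0.19 and Ndufb3 0.56 ± 0.14 up, 0.339), G2/M genes (23, the checkpoint kinase gene Bub1 up by 0.53 ± 0.10, 0.872), p53 targets (16, Rps27l up by 0.49 ± 0.10, 0.872), cholesterol synthesis genes (22, 0.872) and eIF2 kinases and subunits (16, Eif5 up by 0.43 ± 0.11, 0.271) did not pass by camera. Adjusted over the list alone, 4 ATF4 targets were up and 1 down, 7 oxidative phosphorylation genes up and 2 down, and 2 eIF2 kinases and subunits up, while the other lists kept their counts. The G2/M, p53 and cholesterol lists had a negative median and test direction and a positive mean. Of the marker lists, Gp5 fell by 0.41 ± 0.10 and Apoa1 rose by 1.08 ± 0.24 at 4.46 CPM. Many of these single calls in footprints did not hold throughout. Of 20 alternatives, 11 ended the call for Ndufb3, 11 for Eif5, 9 for Slc4a1, 7 for Cox6c, 7 for Xbp1, 6 each for Bub1, Rps27l and Gp5 and 5 for Ndufa5, and of 18, 8 for Atf3 and 7 for Apoa1.

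Translational efficiency, footprints per RNA, was the measure the series design names for translation. Atf4 rose most, by 2.02 ± 0.14 (log2 ± SE, 6 footprint and 6 RNA libraries, edgeR adjusted p = 3.18e-07), with nearly all of its footprint change at steady RNA. Ddit3 rose by 1.60 ± 0.31 (adjusted p = 0.0224), Ppp1r15a by 0.97 ± 0.20 (0.0255), Ifrd1 by 0.90 ± 0.14 (0.00852), Ibtk by 1.1 ± 0.16 (0.00709), Pnrc2 by 1.11 ± 0.18 (0.00995) and Slc35a4 by 1.90 ± 0.30 (0.00900) at 3.20 CPM. For Slc35a4 unscaled CDS footprints went from 29 reads untreated to 67 under tunicamycin, and leader reads from 376 to 305. The tunicamycin footprint libraries were smaller, so the lower leader count does not show a fall. Hspa5 went the other way in its value, -0.49 ± 0.12, without passing (adjusted p = 0.0594; it passed under 6 of 26 alternatives), and the ER chaperone gene Hyou1 fell by 0.54 ± 0.12 (0.0302). Atf4, Ifrd1, Ibtk and Pnrc2 passed under each of 26 alternatives. Ddit3 did not pass without untreated footprint replicate 2 (0.0696), tunicamycin footprint replicate 3 (0.0715) or untreated RNA replicate 2 (0.0625), and Ppp1r15a not without untreated footprint replicate 1 (0.0576), tunicamycin footprint replicate 3 (0.0859), untreated RNA replicate 2 (0.0821) or tunicamycin RNA replicate 3 (0.0620).

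**Figure D3:**
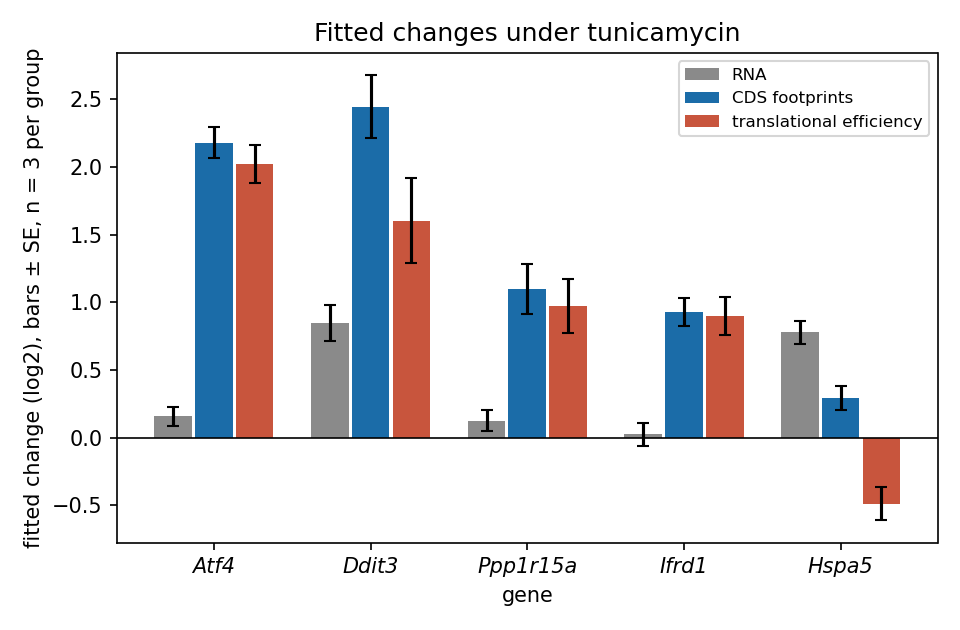
Bars give the fitted log2 change under tunicamycin in RNA, CDS footprints and translational efficiency for 5 stress genes, with SE and 3 libraries per group. Atf4 reached 2.02 in translational efficiency and Hspa5 -0.49, which did not pass but did under 6 of 26 alternatives.

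The other large increases in translational efficiency were Med24 (1.81 ± 0.41), Fbxl12 (1.69 ± 0.34), Hist1h2ae (1.66 ± 0.31), Usmg5 (1.59 ± 0.25), Scoc (1.52 ± 0.21), the muscle membrane gene Popdc2 (1.37 ± 0.26), the synaptic scaffold gene Bsn (1.33 ± 0.22), the vacuolar ATPase gene Atp6v1f (1.3 ± 0.26) and Ndufab1 (1.13 ± 0.27). Leader shares of 49.9%, 44.8%, 53.6%, 39.7% and 46.5% in untreated cells for Fbxl12, Hist1h2ae, Usmg5, Scoc and Ndufab1 came with little change under tunicamycin (49.4%, 45.4%, 54.4%, 41.0% and 48.4%), so shared leader and CDS reads are again possible there. Translational efficiency fell for Sclt1 (-1.17 ± 0.21), the actin cross-linker gene Flna (-0.85 ± 0.21), Aak1 (-0.79 ± 0.19), Smarcal1 (-0.77 ± 0.14), Lamc1 (-0.74 ± 0.15), Prdm4 (-0.72 ± 0.16), Fam199x (-0.71 ± 0.17), Mast2 (-0.70 ± 0.16), Wac (-0.69 ± 0.13), Map4k4 (-0.69 ± 0.15) and Mllt1 (-0.64 ± 0.13). Of 26 alternatives, 15 ended the call for Fam199x, 14 for Flna, 14 for Aak1, 13 for Ndufab1, 12 for Mast2, 10 for Prdm4, 10 for Med24 and 9 for Map4k4. Fewer, 6 each, ended it for Fbxl12, Atp6v1f and Lamc1, 4 each for Popdc2 and Mllt1, 3 each for Smarcal1 and Wac and 2 for Sclt1. Of 25, 3 ended it for Hist1h2ae. Med24 did not pass with robust edgeR (0.176), without any 1 of the RNA libraries (0.0518 to 0.0948), without untreated footprint replicate 1 (0.0644) or without tunicamycin footprint replicate 2, where it stood at 1.23 (0.0536).

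Of 9218 genes tested for translational efficiency, 96 rose and 41 fell. These changes are relative to the typical gene (median log2 -0.0112), so a drop or gain common to all mRNAs would not show. The directions were nearer to even with DESeq2 (212 up, 177 down), limma voom (176 up, 139 down) and the replicate block (839 genes, 432 up, 407 down). Of the 96, 79 also rose in footprints, 1 (Ddit3) also rose in RNA and 9 were histone genes. Of the 41, 29 fell in footprints and 0 in RNA. Leaving out 1 RNA library gave 76, 23 and 68 genes without untreated replicates 1, 2 and 3, and 75, 62 and 24 without tunicamycin replicates 1, 2 and 3. Leaving out 1 footprint library gave 85, 32 and 253 without untreated replicates 1, 2 and 3, and 317 and 24 without tunicamycin replicates 1 and 3. Once a trend with gene span was removed 77 passed.

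The eIF2 uORF list rose in translational efficiency (16 measured: 8 up, 0 down, 9 up adjusted over the list alone, median 0.88, camera adjusted p = 1.12e-08, adjusted p = 0.0249 with an estimated correlation). It did not pass with the replicate block and an estimated correlation together. Immediate early genes rose (16 measured, 0 passing, 2 up adjusted over the list alone, 0.000583, adjusted p = 0.0707 with an estimated correlation), with Junb at 0.45 ± 0.12 and Ier2 at 0.43 ± 0.13. TOP mRNAs fell (15 measured, 0 passing, 5 down adjusted over the list alone, 0.000963, adjusted p = 0.333 with an estimated correlation), for example Eef1g (-0.51 ± 0.14), Pabpc1 (-0.91 ± 0.28) and Eef1a1 (-0.43 ± 0.14). ER chaperones fell (29 measured, Hyou1 down, 4 down adjusted over the list alone, 0.00553, adjusted p = 0.423 with an estimated correlation, 0.109 without tunicamycin footprint replicate 1), with Herpud1 at -0.64 ± 0.18 and Pdia4 at -0.70 ± 0.21. ATF4 targets fell (27 measured, 0 passing, 1 down adjusted over the list alone, median -0.11, 0.0387, adjusted p = 0.333 with an estimated correlation), for example Phgdh at -0.46 ± 0.13 and Mthfd2 at -0.34 ± 0.11. With the replicate block more members of the TOP, ER chaperone and ATF4 target lists passed singly as lower, and more immediate early genes as higher. Oxidative phosphorylation genes rose (43 measured, Ndufa5 up by 0.56 ± 0.11, 6 up adjusted over the list alone, 0.0387, adjusted p = 0.666 with an estimated correlation). That list did not pass with the replicate block (0.0638) or with library size only (0.0514).

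The ATF4 target list did not pass in translational efficiency without untreated footprint replicate 1 (0.0811) or 2 (0.0503), tunicamycin footprint replicate 1 (0.0671) or 2 (0.121), untreated RNA replicate 3 (0.0871) or tunicamycin RNA replicate 2 (0.0845). The oxidative phosphorylation list did not without untreated footprint replicate 1 (0.137) or 2 (0.0581), tunicamycin footprint replicate 1 (0.0671) or 2 (0.121), untreated RNA replicate 2 (0.114) or 3 (0.0871) or tunicamycin RNA replicate 3 (0.326). Ribosomal proteins did not pass as a list (46 measured, with Rps25 0.71 ± 0.12, Rplp1 0.73 ± 0.17 and Rpl41 0.98 ± 0.23 up, adjusted p = 0.253). Neither did tRNA synthetases (20, 0.259), erythroid haem and membrane genes (24, 0.502, median 0.05 and mean -0.01), erythroid transcription factors (19, 0.391), G2/M genes (23, 0.259), p53 targets (16, Rps27l up by 0.55 ± 0.13, 0.997, median -0.04 and mean 0.05), cholesterol synthesis genes (22, 0.276) or eIF2 kinases and subunits (16, 0.503, median -0.02 and mean 0.04) by camera. Adjusted over the list alone, 4 ribosomal protein genes were up and 3 down, and 1 gene was up in each of the p53 and eIF2 lists, while the others had 0. Of 26 alternatives, 15 ended the call for Rpl41, 12 for Rplp1, 11 for Rps27l, 10 for Hyou1 and 7 for Ndufa5. Without passing as fitted, Phgdh, Eef1g and Pabpc1 each passed under 6, Herpud1 and Pdia4 under 4, Junb and Ier2 under 3, Eef1a1 under 2 and Mthfd2 under 1.

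Footprints on 5' leaders, where upstream reading frames lie, made up 4.80% ± 0.724 of footprints in untreated and 8.56% ± 1.41 in tunicamycin-treated cells (SD, n = 3), a ratio of 1.78 with every tunicamycin library above every untreated one (exact permutation p = 0.1, the smallest 3 against 3 allows). The CDS share went from 93.1% to 89.4% (p = 0.1, exact) and the 3' UTR share from 2.10% ± 0.107 to 2.00% ± 0.124 (p = 0.4, exact). Gene by gene, the ratio of leader to CDS footprints rose by a median of 0.90 (log2) over 4693 genes, of which 3021 rose and 3 fell. Log2 values given beside leader percents are changes of this ratio. Without tunicamycin replicate 3, 1910 passed. Atf4 moved against this shift. Its leader share fell from 43.2% ± 5.91 to 22.6% ± 1.89 (log2 -1.38 ± 0.24, edgeR adjusted p = 0.000992). The other decreases were the uncharacterised gene D17Wsu92e (18.2% to 12.7%, -0.62 ± 0.25) and Slc35a4 (92.9% to 82.0%, -1.50 ± 0.36). The call for D17Wsu92e ended under 8 of 19 alternatives (adjusted p up to 0.139).

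The heat shock cognate gene Hspa8 rose most, from 3.48% ± 1.01 to 21.7% ± 4.93 of its leader and CDS footprints (2.95 ± 0.30), followed by Ran (2.80 ± 0.34), Dek (2.55 ± 0.34), the ER chaperone gene Calr (2.53 ± 0.39), Psmd13 (2.49 ± 0.33), Uqcrc2 (2.42 ± 0.31), Psat1 (2.37 ± 0.46), Anln (2.35 ± 0.36), the replication clamp gene Pcna (2.33 ± 0.25), the splicing factor gene Srsf3 (2.31 ± 0.30, 28.8% to 66.1%), Top2a (2.28 ± 0.29) and Ptpn7 (2.24 ± 0.36). Hspa5 went from 4.12% ± 0.833 to 12% ± 1.93 (1.67 ± 0.25). Ddit3 (59.6% to 56.2%, -0.21 ± 0.27, adjusted p = 0.480), Ifrd1 (16.9% to 14.6%, -0.25 ± 0.23, 0.325) and Ppp1r15a (31% to 32.7%, 0.13 ± 0.25, 0.648) did not pass. With a TMM factor per column, which sets each gene against the shift of all leaders, 232 genes were higher and 326 lower, and with DESeq2 size factors 219 and 340. On that scale Atf4 stood at -2.32, Ifrd1 at -1.19 (adjusted p = 0.000307), Ddit3 at -1.16 (0.00243), Ppp1r15a at -0.82 (0.0202) and Hspa5 at 0.74 (0.00148).

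**Figure D4:**
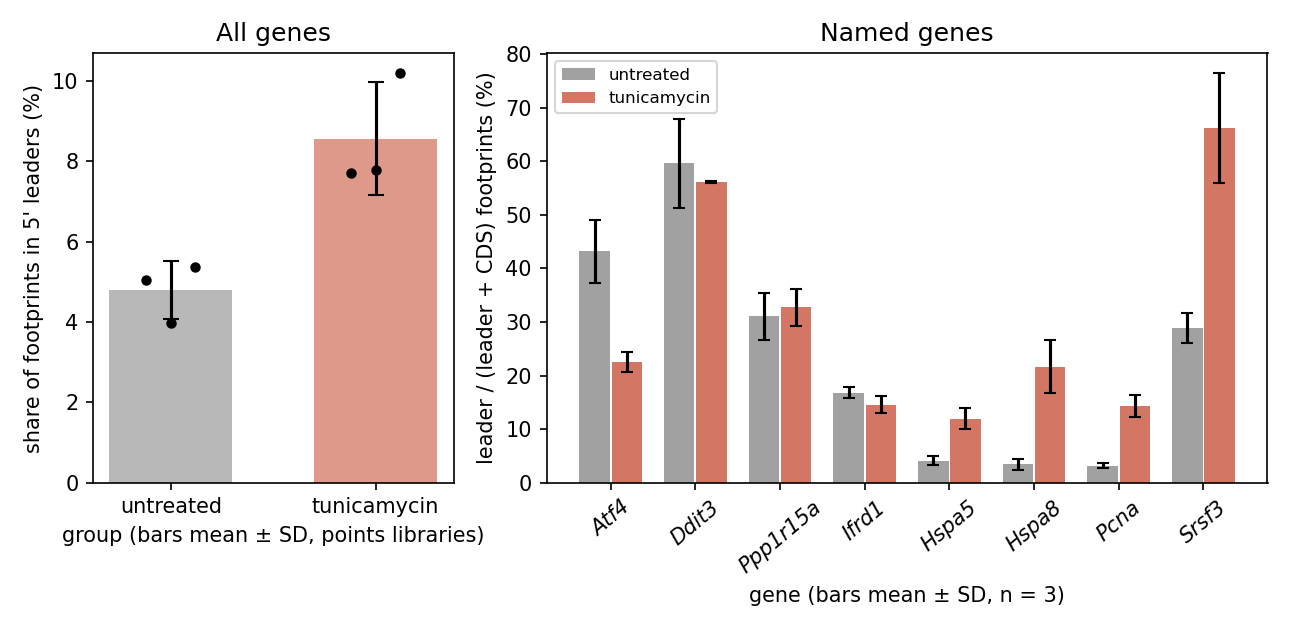
The left panel shows the percent of all footprints lying in 5' leaders per library (points) with the group mean and SD (bars), and the right panel shows the leader percent of leader plus CDS footprints for 8 genes, as mean and SD of 3 libraries. The share over all genes went from 4.80% to 8.56%, while that of Atf4 went from 43.2% to 22.6%.

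Against that general shift the eIF2 uORF list was lower (13 measured: 3 up, among them Eprs by 1.56 ± 0.30, and 2 down, the same 3 and 2 adjusted over the list alone, median -0.15, mean 0.00, camera adjusted p = 3.99e-14, adjusted p = 0.123 with an estimated correlation). Some of its genes had high untreated leader shares (Slc35a4 92.9%, Pnrc2 84.5%, Ddit3 59.6%, Atf4 43.2%), others low ones (Eprs 0.355%). The list was not compared with genes of like untreated share, so a part for that share stays open. G2/M genes were higher (18 measured, 17 up, and 17 up adjusted over the list alone, median 1.39, 0.00168, adjusted p = 0.992 with an estimated correlation), for example Ube2c (2.16 ± 0.32), Cdk1 (1.51 ± 0.27) and Aurkb (1.46 ± 0.26). In the other lists members rose with the shift and the list did not differ from it by camera: tRNA synthetases (15 of 17 up, adjusted p = 0.0743), ER chaperones (15 of 17, 0.0798), erythroid transcription factors (13 of 15, 0.0897), ATF4 targets (12 of 16, 0.298), cholesterol synthesis (16 of 20, 0.298), oxidative phosphorylation (23 of 32, 0.375), erythroid haem and membrane genes (14 of 20, 0.816), TOP mRNAs (6 of 10, 0.809), ribosomal proteins (14 of 28, 0.648), immediate early genes (4 of 8, 0.648), p53 targets (3 of 8, 0.223) and eIF2 kinases and subunits (5 of 7, 0.995). Adjusted over the list alone the counts were 14 for erythroid transcription factors, 25 for oxidative phosphorylation and 18 for cholesterol synthesis, and the same for the other lists.

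Harringtonine footprints, meant to mark initiation, differed for 1 of 3681 genes. The histone gene Hist1h4k rose by 2.02 ± 0.28 (edgeR adjusted p = 0.0159). It did not pass without untreated harringtonine column 2 (0.474) or 3 (0.580), and leaving out untreated column 1 gave 2 genes. The Hist1h4k site with the smallest p, given below, lies nearer the gene's 3' end, so its rise is not shown to be at a start. Atf4 (404 ± 132 and 476 ± 52.6 CPM, 0.23 ± 0.26), Hspa5 (0.15 ± 0.24) and Ifrd1 (0.18 ± 0.54) did not pass (adjusted p = 0.998 each), and Ddit3 and Ppp1r15a had no kept position. The lower genes with the smallest p were the stem cell factor receptor gene Kit (-0.97 ± 0.26), Rpl23a (-0.90 ± 0.25) and Scaf4 (-1.95 ± 0.57), all not passing (0.998). At an unadjusted p under 0.05 there were 133 genes, and DESeq2 passed 2. Ribosomal protein genes fell as a list (73 measured, 0 passing and 0 adjusted over the list alone, median -0.22, camera adjusted p = 0.00209, adjusted p = 0.772 with an estimated correlation), for example Rps19 at -0.70 ± 0.21 and Rps12 at -1.1 ± 0.34, with Rpl6 at 0.76 ± 0.25. The list did not pass without untreated column 1 (0.621) or tunicamycin column 3 (0.422). The other lists tested did not pass (adjusted p from 0.661 to 0.837), with 1 TOP gene up and 1 erythroid transcription factor gene down adjusted over the list alone. The tRNA synthetases had a median of 0.01 and a mean of -0.01.

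Set against RNA, harringtonine reads passed for 0 of 3580 genes by edgeR, with 259 at an unadjusted p under 0.05 and 64 by DESeq2. The genes with the smallest p were the surface marker gene Cd24a (1.88 ± 0.38, adjusted p = 0.286), the proteasome gene Psma7 (1.26 ± 0.29, 0.373) and Eif4b (1.45 ± 0.34, 0.373) on the higher side, and Xbp1 (-1.50 ± 0.35), Scaf4 (-2.13 ± 0.52) and Kit (-1.02 ± 0.26) on the lower side (0.373 each). Atf4 was at 0.09 ± 0.27, Ifrd1 at 0.15 ± 0.49 and Hspa5 at -0.62 ± 0.24 (0.966, 0.968 and 0.551). Leaving out untreated harringtonine column 1 gave 2 genes, and tunicamycin harringtonine column 2 or 3 gave 1 each. Ribosomal proteins fell (72 measured, 0 passing and 0 adjusted over the list alone, median -0.22, 0.00127, adjusted p = 0.512 with an estimated correlation), as in Rpl23a (-0.99 ± 0.26). They did not pass without untreated RNA replicate 1 (0.0562), untreated harringtonine column 1 (0.0820) or tunicamycin harringtonine column 3 (0.0820). ER chaperones fell (13 measured, 0 passing, 1 down adjusted over the list alone, 0.00453, adjusted p = 0.317 with an estimated correlation), with Pdia3 at -0.64 ± 0.23. They did not pass without untreated harringtonine column 3 (0.201) or tunicamycin harringtonine column 1 (0.112). The other lists tested did not pass, from ATF4 targets (13 measured, 0.0824) to erythroid transcription factors (0.791, median 0.02 and mean -0.09) and immediate early genes (0.791, median 0.02 and mean -0.04), with 1 TOP gene up and 1 erythroid transcription factor gene down adjusted over the list alone.

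Single harringtonine sites, which the series design used to look for alternative starts, are given by position as in the deposited files (mm10). The highest was in the beta-globin gene Hbb-bs (chromosome 7, 103827864, 65 nt from the gene's 5' end) with 90306 ± 8266 CPM untreated and 75845 ± 3479 CPM under tunicamycin. Then came sites in Btf3 (chromosome 13, 98316874), Rps6 (4, 86857335), the metallothionein gene Mt1 (8, 94179299), Hist1h1d (13, 23555077), Rpl35 (2, 39005093), Hist1h4c (13, 23698446), Hist1h2be (13, 23585969), the cofilin gene Cfl1 (19, 5490587) and Hist1h2ae (13, 23571112), and none of these 10 passed between treatments. Atf4 had sites at 80255668 on chromosome 15, 485 nt from its 5' end (363 ± 148 and 426 ± 97.9 CPM, log2 0.26 ± 0.31), and at 80256234 (40.2 ± 19.2 and 50.9 ± 46.4 CPM, 0.37 ± 0.59). Ifrd1 had low sites at 40223006 (4.15 ± 3.60 and 15.9 ± 8.52 CPM) and 40223161 (15.2 ± 8.44 and 6.25 ± 2.90 CPM) on chromosome 12, too low to test.

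Of 5123 sites tested 0 passed by edgeR, with 176 at an unadjusted p under 0.05 and 1 by DESeq2. In simulated counts 3.5% of sites changed 2-fold were recovered. Leaving out tunicamycin column 1 gave 4 sites, and tunicamycin column 2 or 3 gave 1 each. The smallest p on the higher side belonged to Hist1h4k (13, 21750253, 1329 ± 289 and 5429 ± 2210 CPM, 2.06 ± 0.29, adjusted p = 0.0646), 301 nt from the gene's 5' end. That gene runs from 21750145 to 21750553, so the site lies nearer its 3' end and was not shown to be a start. Hist2h2bb (2.05 ± 0.50) and Cd24a (2.38 ± 0.59) followed, and on the lower side Rps19 (-0.78 ± 0.22), Osbpl8 (-1.09 ± 0.31) and Ybx1 (-1.73 ± 0.45), all not passing (1.000). At 20 or more reads, 6828 positions were seen in both treatments, 1597 only under tunicamycin and 600 only in untreated cells. The tunicamycin libraries hold more reads.

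Across the 9218 genes tested in both assays, RNA and footprint changes were nearly unrelated (Pearson r = 0.0319, Spearman rho = 0.0346). Genes are not independent replicates, and no p is given. The changes were not large next to their error, which can pull r toward 0. Their SD over genes was 0.140 in RNA and 0.263 in footprints, against median SE of 0.0846 and 0.127. Opposite trends with gene span (Spearman 0.297 in RNA, -0.155 in footprints) can also lower r. The low r therefore does not show that RNA and translation were uncoupled. The sign of r turned without untreated footprint replicate 3 (-0.0601), tunicamycin footprint replicate 1 (-0.00140) or tunicamycin RNA replicate 2 (-0.0213), and r was 0.0894 without untreated footprint replicate 2. Even so, 7 genes rose in both, Atf3, Chac1, Ddit3, Herpud1, Ier2, Polr1a and Trib3, where 0.271 would be shared by independent lists of 16 and 156.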

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

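Tests chosen after the result was seen in this part were the 3' UTR ratio, the span correlation of footprints, the span correlation per library, the calls outside the eIF2 uORF list with the span trend removed, the S-phase genes, the sums over core histone types and the splits of translational efficiency by kind.

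Footprints in 3' UTRs were used gene by gene in no comparison of the report. Of 2015 genes tested for a changed 3' UTR share against the CDS, 9 passed by edgeR (7 up, 2 down), at adjusted p from 0.0308 to 0.0473. No fit without single libraries is given for these, and single histone counts are uncertain. The ratio of 3' UTR to CDS footprints rose (log2) for Smim5 (2.26 ± 0.35 SE), Polr1d (2.59 ± 0.49), Arpc4 (2.00 ± 0.38), Hist2h2bb (1.73 ± 0.33), Tmem261 (1.66 ± 0.32), Rtn3 (1.43 ± 0.28) and the metallothionein gene Mt2 (0.83 ± 0.17). It fell for Hist1h3h (-1.62 ± 0.28) and Hist1h4h (-1.26 ± 0.22).

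The leader share of footprints rose in most genes. Without the 188 genes with the most leader reads the ratio of tunicamycin to untreated was 1.82 (1.65 to 1.93 leaving out 1 library), which argues against a few genes as the source. The 3' UTR ratio was 0.954 (0.929 to 0.988), which argues against a general gain of reads outside coding sequence. Harringtonine reads at kept positions upstream of each gene's tallest site went from 5.34% to 5.18%, a ratio of 0.970 (0.946 to 0.997). The mean share there did not rise. The tallest site was not shown to be the annotated start, and positions with few reads were not kept. The ratio therefore cannot decide whether more starts in leaders were used. A treatment difference in how cycloheximide acts on leaders was not tested and could account for the shift. The 10 splits of the 6 libraries are too few for a share under 0.05, with 3024 genes in the real split and 0 as the highest other, and 2 lists against 1.

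Changes in translational efficiency followed gene span (Spearman -0.307), but the libraries of the 2 treatments overlapped in their own correlation with span (RNA -0.355 to -0.0112 untreated and -0.120 to 0.271 treated, exact permutation p = 0.3, and footprints -0.118 to 0.229 and -0.172 to 0.0494, p = 0.2). Footprint changes fell with span too (-0.155, -0.236 to -0.103 leaving out 1 library), which argues against a trend of the RNA libraries (0.297) as the whole source. All 8 eIF2 uORF list genes called in translational efficiency, 100%, passed with the trend removed, with a median size of 1.11 before and 1.08 after (median SE 0.181 and 0.173), which argues against span for these. Of the other 129 genes 60, or 46.5%, passed, and all 129 kept their sign with a median size of 0.69 before and 0.61 after (median SE 0.141 and 0.134). The 69 that did not pass went from 0.64 to 0.54 (SE 0.150 to 0.142), 27 of them at a p that had passed before, so these calls ended through smaller sizes and a stricter threshold, and a part for the trend stays open.

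Histone footprints rose, and histone RNA had a median change of -0.52. The 18 S-phase genes had a median footprint change of 0.00783 (-0.0219 to 0.0293 leaving out 1 library), an SD of 0.140 and a highest value of 0.173, against a histone median of 0.719, which argues against more cells in S phase as the whole source. Reads shared between copies stay open for all types together, since H1 summed to 0.285. The lowest core type summed to 0.715, which argues against reads only moving between copies of a core type. A read counted at several copies would raise their sum as well, so the sums cannot tell how many copies rose. With the span trend removed 26 of 33 calls, 78.8%, passed, with a median size of 1.08 before and 0.88 after, so part may follow span.

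For the remaining comparisons of 3 against 3 the 10 splits are too few for a share under 0.05. The real and highest other counts were 16 and 4 genes for RNA (1 split as large), 6 and 5 lists for RNA (1), 239 and 0 genes for cycloheximide footprints (1), 4 and 5 lists (2), 1 and 15 genes for harringtonine (2), 1 and 2 lists (4), and 0 and 0 sites (10). Among the RNA splits that part the 3 pairs, the highest other count was 0 genes and 5 lists. For translational efficiency, the real split alone, 1 of 100 drawn from 200, gave its 137 genes (highest other 122), and 1 of the 36 that part the 3 RNA pairs (highest other 32). These splits vary the RNA and footprint groups together, so they argue only against chance in both assays at once for the count. With the footprint groups kept and RNA split otherwise, 1 of 11 gave as many (highest other 122), too few for a share under 0.05, so chance stays open for the RNA side. The footprint libraries alone have 10 splits, also too few, so chance stays open for that side as well. At least its 6 lists came from 5 splits (highest other 8), so chance is not excluded for the lists. For harringtonine against RNA the real count of 0 genes, which 100 of 100 drawn splits reach by definition (highest other 57), tests nothing, and 15 gave at least its 2 lists (highest other 4), so chance is not excluded for the lists. The splits with 15 and 57 genes set untreated harringtonine columns 1 and 3 and tunicamycin column 1 against the rest, which keeps both columns 1 and both columns 2 together.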

How the results depend on the processing

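Removal of the span trend, column scaling, the fits without histone genes and those without the libraries numbered 1 were chosen after the data were seen. Unless a cause follows from the setting (fewer libraries or genes, a stricter threshold), the cause was not tested. In RNA, 16 genes became 112 with DESeq2, 43 with limma voom, 122 without a filter, 9 at 5 CPM or more, 410 with the replicate block, 4 at FDR 0.01, 8 at 1.5-fold, 54 without the libraries numbered 1, and 3 to 26 leaving out 1 library. In cycloheximide footprints, 239 became 381 with voom, 573 without a filter, 885 with the replicate block (522 up, 363 down), 51 at FDR 0.01, 114 at 1.5-fold, and 58 to 431 leaving out 1. In translational efficiency, 137 became 389 with DESeq2, 315 with voom, 403 without a filter, 839 with the replicate block (432 up, 407 down), 16 at FDR 0.01, 77 with the span trend removed, and 23 to 317 leaving out 1. For harringtonine genes, 1 became 2 with DESeq2, 0 at FDR 0.01, and 0 to 2 leaving out 1. Against RNA, 0 became 64 with DESeq2, 1 with voom, 1 with robust edgeR, and 0 to 2 leaving out 1. Harringtonine sites went from 0 to 4 leaving out 1. For the leader share, 3024 genes became 559 with DESeq2 size factors, 527 with library size, 553 with upper quartile, 558 with column scaling (each of which removes the general shift), 1773 at 5 CPM or more, 1683 at FDR 0.01, and 1910 to 3001 leaving out 1. Lists passing with an estimated correlation numbered 0 for RNA, 0 for footprints, 1 for translational efficiency, 0 and 0 for harringtonine alone and against RNA, and 0 for the leader share. With fry they were 2 for footprints, 0 and 0 for harringtonine alone and against RNA, and 13 for the leader share, where fry does not compare a list with other genes and the eIF2 uORF list turned direction (0.912). Leaving out 1 library gave 5 to 7 lists in RNA, 2 to 5 in footprints, 3 to 7 in translational efficiency, 0 to 1 and 1 to 2 in harringtonine alone and against RNA, and 2 to 3 in the leader share. The correlation of RNA and footprint changes ran from -0.0601 to 0.0894, turning also to -0.0213 and -0.00140. Values that turned sign, none of them passing as reported, were Ifrd1 RNA (-0.0433 and -0.00805, up to 0.112), Ifrd1 harringtonine (-0.0924, -0.0271, -0.0373, -0.0716, up to 0.785), Hspa5 harringtonine (-0.0393, up to 0.280), Atf4 harringtonine against RNA (-0.0429, -0.0341, -0.0122, up to 0.367), Ifrd1 harringtonine against RNA (-0.151, -0.0472, -0.0892, -0.121, up to 0.780), Ddit3 leader share (-1.17 to -1.08 with the 4 other scalings, all passing, and -0.399 to 0.0709 leaving out 1) and Ppp1r15a leader share (-0.832 with DESeq2 size factors, -0.777 library size, -0.737 upper quartile, -0.820 column scaling, all 4 passing, and -0.0410 and -0.000945, up to 0.235, leaving out 1). Of the alternatives run for genes named as passing, 186 of 262 kept the call in RNA, 761 of 941 in footprints, 679 of 882 in translational efficiency and 365 of 378 in the leader share. Of those run for genes named as not passing, 65 of 474, 16 of 60, 53 of 312 and 8 of 57 came to pass. In cycloheximide footprints each sample correlated best with its own number across treatments (0.348, 0.0943 and 0.277), a hint from the data and not the design. With the replicate block all 16 RNA, 239 footprint and 137 translational efficiency calls passed, and beyond the RNA values given in the report it changed no other call of a gene or list named there in RNA. In translational efficiency the eIF2 uORF list did not pass with block and estimated correlation together (0.107), the oxidative phosphorylation list did not pass with the block (0.0638) or library size only (0.0514), and single genes passing with the block were 7 TOP mRNAs down, 7 ER chaperones down, 3 ATF4 targets down and 3 immediate early genes up. No paired analysis of harringtonine counts was run. The sources tie its columns to treatments and to no numbered sample, so harringtonine footprints, harringtonine against RNA and sites have no block. Whether columns of the same number pair across treatments was not checked. A pairing that these fits leave out therefore stays open as a reason for their few calls. In simulated counts 25.5% of harringtonine genes and 3.5% of sites changed 2-fold were recovered, and 29% for the leader share. Depth was not told apart from the spread of replicates there. For the leader share 200 of 4693 simulated genes were changed, while 3024 passed in the data, so the 29% may not describe that test.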

Other observations

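No test of this part was chosen after its result was seen.

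Outside the lists, the leader share in untreated cells was set against the later change of translational efficiency, as the hypothesis that mRNAs with more leader footprints gained translation under stress. The Spearman correlation over genes with 50 or more reads was 0.208 (median of 3 untreated libraries, 0.185 to 0.238), each taken from 1 library and set against the change fitted without it. Without the eIF2 uORF list it ran from 0.183 to 0.235, though so short a list can hardly move a correlation over 7766 or more genes. With the span trend removed it was 0.199 (0.174 to 0.231), which argues against span as its source. With untreated libraries 1, 2 and 3 in turn, 29 of 1568, 14 of 1553 and 83 of 1584 genes with the highest leader shares rose in translational efficiency, and 7, 2 and 17 of as many with the lowest. Reads counted as both leader and CDS were not separable here and could raise it, so 0.208 stays a hypothesis found on these data.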
